A study of Mus musculus with 17 samples.

How the data were processed

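Bulk RNA sequencing was made from brain cells of mice in 5 groups, and the labels give 17 libraries. Per the labels' protocols, living CD45+CD11b+ cells (DAPI-negative) were sorted straight into TRIzol LS, total RNA was cleaned up on columns, and libraries were made with the SMART-Seq v4 Ultra Low Input kit and sequenced on a NovaSeq instrument. The cells were labelled microglia in 3 groups without treatment and circulation-derived myeloid cells in 2 groups that had received bone marrow plus PLX5622, a CSF1R inhibitor that depletes microglia.

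The deposited table holds 1 normalized signal per gene and library for 13501 gene symbols. Per the submitters' processing notes, the authors used bcl2fastq, STAR 2.5.2b, HTSeq, RSEM and DESeq2 (version given as 3.17) with genome builds mm10 and GRCm38.p6. The role of HTSeq as against RSEM, the gene annotation and any filter are not given in the sources used here. The values themselves were tested: within a tolerance of 0.02, at least 99.99% of the values of each library were whole multiples of 1 step per library, so the deposited signal is a read count divided by 1 size factor per library. In library S20 the step was so near 1 that rounding alone could give whole multiples at low values. The recovered read totals ran from 16044078 to 30606394 per library with a median of 19254498, and size factors recomputed with DESeq2 differed from the deposited ones by at most 0.01%. Factors from the TMM method of edgeR differed by up to 7.3%. No reads were realigned.

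Libraries are named by the sample numbers in the column names (S20 to S36). Outside the normal group the columns carry the group but no distinct replicate number, so that libraries could be assigned to groups only. The labels do not say whether replicates are separate animals, and p-values measure the spread between these samples. S22 and S23, S25 and S27, and S30 and S31 lay closer together (chi-square per degree of freedom 6.21, 9.99 and 5.01) than the other pairs within groups (13.89 to 140.25). If such a pair came from 1 animal, the replicates are overstated and the standard errors too small. Symbols were matched to GENCODE vM21, which supplied positions on GRCm38. All 6 sex-linked genes of a list fixed for checking samples were missing from the table, so that this check was not made.

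Values were analysed as log2(value + 1). Genes with a value of 10 or more in at least 3 libraries were kept, which left 12074 genes and removed 1427. One limma model (version 3.58.1, lmFit and eBayes with trend, in R 4.3.3) with a mean per group was fitted to all 17 libraries, and 7 contrasts were taken from it. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and all such tests were two-sided. Levels are given as mean ± SD of the deposited normalized read count, and changes as log2 fold change with the standard error (SE) of the limma model.

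Gene lists for microglial states, pathways and other cell types were fixed before the data were examined. For each list with at least 5 tested members, the counts of called genes were taken over all genes and again adjusted over the list alone. The list was also tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists within a comparison. The preset camera test decided the call. The genes called in a contrast were tested in another as an up set and a down set, with p adjusted over the 6 sets, an adjustment added after the values were seen.

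The rule for named genes was also fixed before the data were examined, while the lists described in each comparison, whose members it names, were chosen after the results were seen. It takes Trem2 and Tyrobp, the 8 called genes with the largest rise and the 8 with the largest fall per comparison, and up to 4 members of each described list with the smallest p. The largest changes were taken among genes with no overlap between the libraries of the groups and a mean above the median of tested genes, without predicted genes and pseudogenes. For the interaction the condition of no overlap was dropped.

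The procedure was tested on simulated counts with 50 genes changed at each of 4 fold sizes. Changed genes were drawn from those with a mean of at least 50 reads, and noise was drawn separately for each library. Pairs of libraries closer than the rest were not simulated, so recovery in the real data may be lower. At 2-fold it recovered 50% of the changed genes for 5xFAD against normal microglia (11890 genes run), 62% for Trem2 in microglia (11873), 66% for Trem2 in transplanted cells (11884), 54% for wild-type transplant against wild-type microglia (11874), 66% for knockout transplant against knockout microglia (11897), 56% for wild-type transplant against knockout microglia (11897) and 36% for the interaction (11898). At 4-fold it recovered 98%, 94%, 98%, 88%, 98%, 96% and 86% in the same order.

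The alternatives fixed beforehand were 2 other pseudocounts, no filter and a stricter filter, quantile normalization, upper-quartile rescaling, a model of the compared groups only, array weights, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, an added 2-fold threshold, and leaving out each replicate in turn. A replicate block was planned and not run. Further alternatives were chosen after seeing the data: the closest pairs of libraries averaged, S25 and S27 left out, S30 and S31 left out, and the neutrophil list score as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.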

Results

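The data are normalized read counts of sorted CD45+CD11b+ brain cells from mice with and without the 5xFAD transgenes, which produce brain amyloid. Normal microglia (3 libraries) came from mice without 5xFAD. Microglia of 5xFAD mice were either Trem2 wild type (3 libraries) or Trem2 knockout (3 libraries). Transplanted cells were circulation-derived myeloid cells in Trem2 knockout 5xFAD mice after bone marrow transplant plus PLX5622, from Trem2 wild-type donors (4 libraries) or Trem2 knockout donors (4 libraries). Read totals ran from 16044078 (S36) to 30606394 (S35). The origin of the cells and the treatment changed together, so that contrasts between transplanted cells and microglia cover both. The host of every transplant was Trem2 knockout, so wild-type transplanted cells and wild-type microglia also differed in the Trem2 genotype of the mouse around them.

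Trem2, a lipid-sensing receptor of myeloid cells on chromosome 17 (48346401 to 48354147, GRCm38), followed the labels in every library. Its normalized read count was 33680 ± 3323 (SD, n = 3) in normal microglia, 51270 ± 1868 (n = 3) in wild-type 5xFAD microglia and 5282 ± 824 (n = 3) in knockout 5xFAD microglia. In transplanted cells it was 45490 ± 8857 (n = 4) with wild-type donors and 4499 ± 601 (n = 4) with knockout donors. Trem2 was higher in wild-type cells by 3.29 on the log2 scale in microglia (SE 0.161, adjusted p = 5.6e-10) and by 3.33 in transplanted cells (SE 0.14, adjusted p = 7.92e-11). Its signaling partner Tyrobp gave 0.40 in microglia (adjusted p = 0.253) and 0.35 in transplanted cells (adjusted p = 0.197), neither past the threshold.

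**Figure D1:**
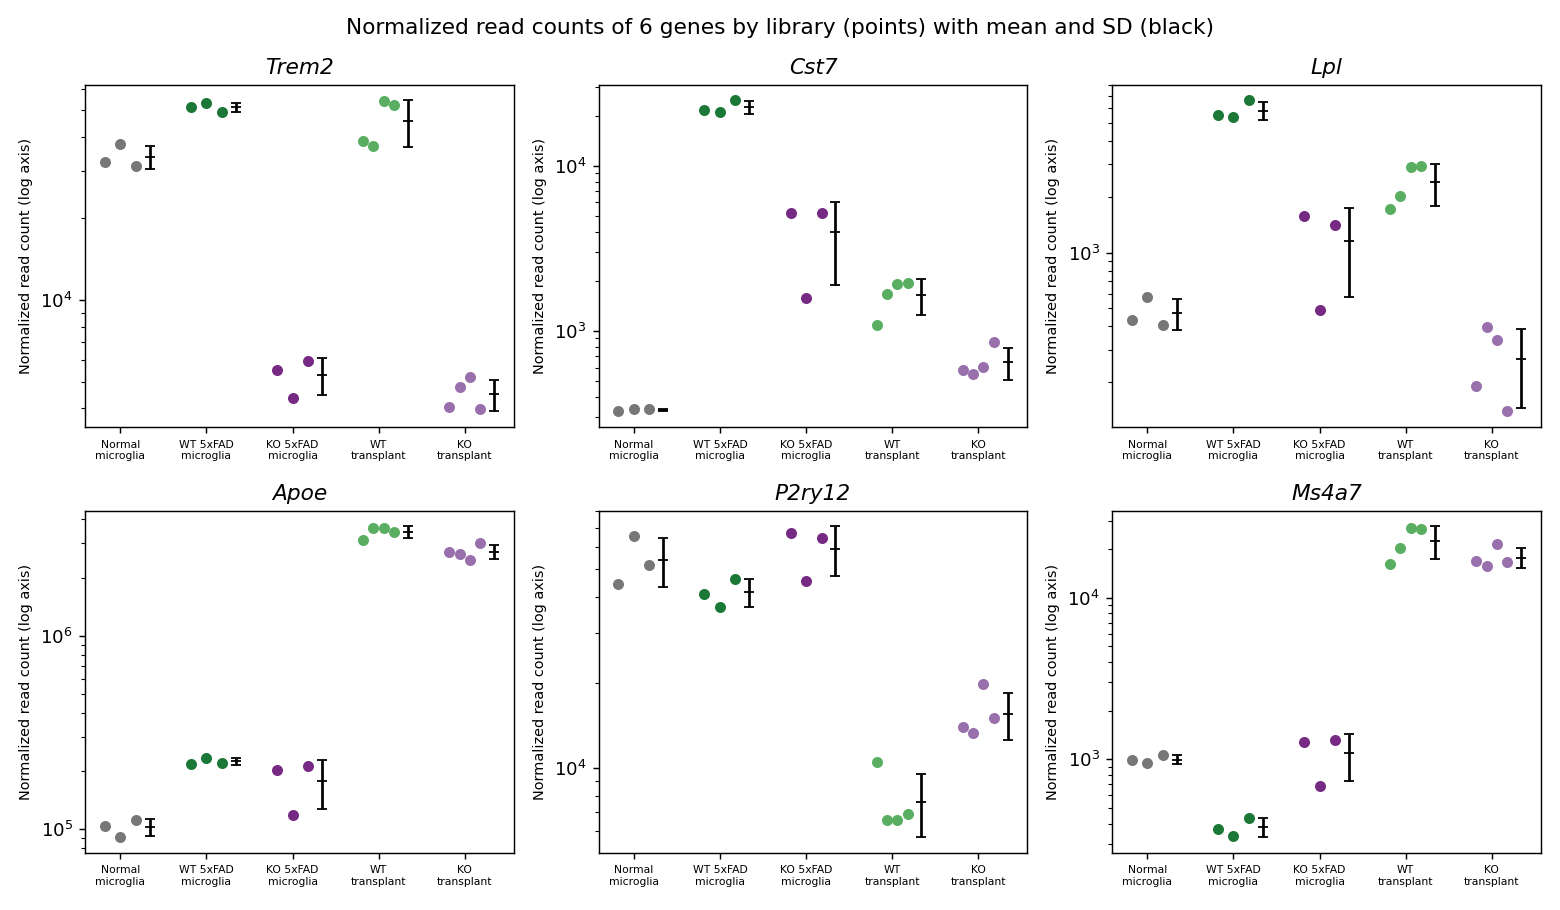
Normalized read counts on a log axis for 6 genes in the 5 groups. Each point is 1 library, and the black marks are the mean and SD of the group. Lpl was higher in wild-type than in knockout cells of both origins, and Apoe and Ms4a7 were higher in transplanted cells than in microglia.

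The first comparison asked how Trem2 wild-type microglia respond to the 5xFAD background. Genes of the disease-associated microglia (DAM) state rose together: 27 of the 29 tested genes of the stage 2 list rose and 0 fell, with a median log2 fold change of 3.03 (28 rose when adjusted over the list alone). Cst7, an inhibitor of lysosomal cysteine proteases, went from 332.5 ± 6.08 to 22580 ± 2013 (n = 3 each). Itgax (CD11c) rose by 3.66, Ank, a pyrophosphate transporter, by 3.44 and Axl, a receptor for apoptotic cells, by 2.06. In the stage 1 list 6 of 10 genes rose (9 adjusted over the list alone; adjusted p = 0.0659 with an estimated correlation), among them Apoe (1.13), Ctsb (0.92), Ctsd (0.84) and Ctsz (0.83). Homeostatic microglia genes moved the other way, with 3 of 24 lower and 0 higher (8 lower adjusted over the list alone) and a median of −0.37. Ecscr fell by 1.00, P2ry13 by 0.47 and Olfml3 by 0.43.

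Metabolic and lysosomal groups rose with the DAM genes, though some of these lists share members with the DAM lists. The lipid list shares Lpl, Fabp5, Ch25h and Plin2 with stage 2 and Apoe with stage 1. The lysosome list shares Ctsl with stage 2 and Ctsb, Ctsd and Ctsz with stage 1, and the glycolysis list shares Hif1a with stage 2. In every comparison these lists are therefore not separate evidence. Of 21 glycolysis and hypoxia genes 15 rose (17 adjusted over the list alone; median 0.68), including Egln3 (4.64), Hif1a (1.54), Pkm (1.07) and Slc16a3 (0.97). Of 22 lipid handling genes 9 rose and 2 fell (10 and 3 adjusted over the list alone; median 0.67), led by Fabp5 (3.72), Lpl (3.64), Ch25h (3.29) and Acaca (2.49). Lysosome genes rose in 9 of 27 cases (15 adjusted over the list alone; median 0.35), with Gusb at 0.79. In cholesterol synthesis 2 of 23 rose (15 rose and 1 fell adjusted over the list alone; median 0.49), namely Sqle (1.59) and Hmgcs1 (0.64), while Fdft1 was 0.38 (adjusted p = 0.0646).

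The inflammatory, early response and antigen presentation lists passed camera only with the preset correlation. The cytokine and NF-kB list had 8 of 22 genes higher (13 adjusted over the list alone; median 0.67, adjusted p = 0.0659 with an estimated correlation), with Ccl3 at 3.44, Ccl4 at 3.27, Nfkbiz at 2.28 and Cd83 at 1.20. Immediate early genes, which also respond to tissue dissociation, rose in 10 of 21 cases (14 adjusted over the list alone; median 0.91, adjusted p = 0.0659 with an estimated correlation), with Atf3 at 2.48, Egr2 at 2.43, Ier3 at 2.02 and Klf4 at 1.90. Interferon response genes rose in 5 of 27 cases (18 adjusted over the list alone; median 0.93, adjusted p = 0.156 with an estimated correlation), with Oasl2 at 1.38, Usp18 at 1.36 and Oas1a at 1.24. Of 9 genes of antigen presentation by MHC class II 4 were lower (1 higher and 7 lower adjusted over the list alone; median −0.76, adjusted p = 0.145 with an estimated correlation): H2-Eb1 (−1.56), H2-Aa (−1.33), H2-Ab1 (−1.24) and Cd74 (−1.13).

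The neutrophil and endothelial lists also passed camera with the preset correlation only. Neutrophil genes were lower in 5xFAD microglia in 4 of 14 cases (10 adjusted over the list alone; median −1.38, adjusted p = 0.135 with an estimated correlation), namely Camp (−1.82), S100a9 (−1.69), Ngp (−1.54) and S100a8 (−1.54). Endothelial genes were higher in 2 of 12 cases (7 adjusted over the list alone; median 1.89, adjusted p = 0.162 with an estimated correlation), Flt1 (2.63) and Vwf (1.91), while Tek (4.16, adjusted p = 0.0548) and Ly6c1 (2.01, adjusted p = 0.0775) did not pass. The largest other rises were Gpnmb (6.51) and Igf1 (3.40), and the other large falls were Mgl2 (−1.69), Tmem52 (−1.50) and Ms4a7 (−1.39). Tyrobp rose by 0.96 and Trem2 by 0.61. Mitochondrial reads were 0.12 to 0.14% in 5xFAD microglia and 0.06 to 0.08% in normal microglia. Mitochondrially encoded genes had a median of 1.03 (4 of 12 higher adjusted over the list alone, adjusted p = 0.315 with an estimated correlation) and ribosomal protein genes 0.28 (adjusted p = 0.529 with an estimated correlation). Monocyte genes had a median of −0.86 (9 of 17 lower adjusted over the list alone, adjusted p = 0.0659 with an estimated correlation).

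In total 342 genes rose and 115 fell of 12074 tested, and 222 and 55 of these changed at least 2-fold. The libraries of the groups did not overlap in 33.6% of tested genes, against 10% from chance alone with 3 against 3. Genes named for the largest changes were chosen for having no overlap, and the other called named genes had none either. With an estimated correlation the camera call held for DAM stage 2 (adjusted p = 0.0153), homeostatic (0.0279), cholesterol (0.00365), and lysosome, lipid and glycolysis (each 0.0367). Of 51 called genes under the rule 39 kept their call without any 1 library. Among the others, Trem2, Olfml3, Hmgcs1, S100a8 and Vwf lost it without any of the 6. P2ry13 and Ngp lost it without 5 each (the exceptions S36 and S21), and Camp, S100a9, Sqle and Oas1a without 4 each. The count fell to 272 without S22, 280 without S23, 289 without S20, 295 without S24 and 302 without S36. It was 1757 in a model of these groups only, 2227 with array weights, 769 with DESeq2 and 247 with the closest libraries averaged.

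The next comparison asked what Trem2 changes in resident 5xFAD microglia. Of 29 DAM stage 2 genes 9 were higher in wild-type microglia and 0 lower (16 higher adjusted over the list alone; median 1.20). The list call was lost with an estimated correlation (adjusted p = 0.185). Ank was 9903 ± 630 in wild-type and 1370 ± 146 in knockout microglia (n = 3 each), a log2 difference of 2.86. Itgax differed by 2.82, Cst7 by 2.70 and Axl by 2.13. Other large differences were Lpl (2.5), Csf1 (2.40), a growth factor for microglia, and Sulf2 (2.13). The median depended on the library: it was 0.56 without S26 and 2.93 without the other knockout libraries S25 and S27. S26 lay nearer to normal microglia (Cst7 at 1576; second principal component 17.3, against 32.9 to 41 in normal microglia, −31 in S25 and −32.3 in S27). S25 and S27 also held more mitochondrial reads (0.26 and 0.25% against 0.07% in S26) and more Lars2 reads, a gene looked at after the values were seen (1.69 and 2.09% against 0.82%). Trem2 followed the label of S26, and the sources used here do not settle whether it differs from S25 and S27 in biology, in handling or in another part of its label.

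Of the next lists only cholesterol synthesis kept its camera call with an estimated correlation. Lysosome genes were higher in 9 of 27 cases and lower in 0 (13 higher adjusted over the list alone; median 0.33, adjusted p = 0.0928 with an estimated correlation), with Gusb at 0.80, Ctsd at 0.79, Hexa at 0.61 and Tpp1 at 0.54. In cholesterol synthesis 4 of 23 were higher (10 adjusted over the list alone; median 0.43), among them Dhcr7 (0.96) and Fdft1 (0.43). The cytokine list had 8 of 22 higher (10 higher and 1 lower adjusted over the list alone; median 0.28, adjusted p = 0.41 with an estimated correlation), with Nfkbiz at 1.54, Tnfaip3 at 1.53, Cd83 at 0.92 and Nfkbia at 0.90. Immediate early genes were higher in 7 of 21 cases (17 adjusted over the list alone; median 0.90, adjusted p = 0.223 with an estimated correlation), with Egr2 at 2.30, Dusp1 at 1.24, Ier3 at 1.24 and Zfp36 at 0.97. MHC class II genes were lower in 4 of 9 cases and higher in 1 (5 and 1 adjusted over the list alone; median −0.67, adjusted p = 0.41 with an estimated correlation), with H2-Eb1 at −1.27, H2-Aa at −1.23, H2-Ab1 at −1.05 and H2-Oa, which restrains peptide loading, at 0.73.

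Knockout microglia libraries held far more RNA of neutrophil and monocyte marker genes. Of 14 neutrophil genes 10 were lower in wild-type microglia and 0 higher (12 lower and 1 higher adjusted over the list alone), with a median of −4.21. S100a8, an abundant neutrophil protein, had 954 ± 200 normalized reads in wild-type and 24340 ± 12760 in knockout microglia (n = 3 each). S100a9 differed by −4.5, Camp by −4.44, Mmp8 by −4.30, Ngp by −4.20, Lcn2 by −3.98, Ltf by −3.88 and Anxa1 by −3.84. Monocyte genes were lower in 15 of 17 cases (16 adjusted over the list alone; median −2.06), with Ly6c2 at −3.62, Plac8 at −3.54, Hp at −3.47 and S100a6 at −3.23. Genes typical of brain macrophages of hematopoietic origin were lower in 6 of 14 cases (3 higher and 10 lower adjusted over the list alone; median −0.65), with Klra2 at −2.0, Clec12a at −1.89, Ms4a7 at −1.46 and Ms4a6b at −0.61. T and NK cell genes were lower in 3 of 16 cases (7 adjusted over the list alone; median −1.50, adjusted p = 0.41 with an estimated correlation): Prf1 (−2.90), Gzma (−2.61) and Nkg7 (−2.58), with Cd8b1 at −3.03 (adjusted p = 0.0612). Every knockout microglia library had a higher mean log2 value of the neutrophil list (S26 10.14, S25 11.69, S27 11.86) than the wild-type libraries (7.19 to 7.39).

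In all, 313 genes were higher in wild-type microglia and 302 lower, 117 and 245 of them at least 2-fold. More genes were lower than higher with upper-quartile rescaling (337 and 247), edgeR (312 and 257), quantile normalization (359 and 325), DESeq2 (522 and 479), a model of these groups only (159 and 119) and without any 1 library except S26. The groups did not overlap in 22.2% of genes (10% from chance alone). Nor did the called named genes overlap, though those with the largest changes were chosen for this. The estimated correlation kept the calls of monocyte (adjusted p = 0.00915), cholesterol (0.0123), neutrophil (0.0317) and hematopoietic-origin genes (0.0461). Without S26 the preset call ended for MHC class II (adjusted p = 0.132, median −0.44) and cytokine genes (adjusted p = 0.127). Without S25 and S27 the medians were −1.15 for MHC class II, 0.66 for cytokine, 0.36 for immediate early and −0.19 for hematopoietic-origin genes. Without both, 15 of the 47 called named genes lost their call, among them Dusp1 (0.49), Zfp36 (0.37), H2-Oa (0.42), Ms4a7 (−0.84) and Ms4a6b (−0.30), while Clec12a was −1.06, Prf1 −4.58 and Gzma −4.28. Of 47 called genes under the rule 34 kept their call without any 1 library. Among the others, 4 genes, Fdft1 and Ms4a6b among them, lost it without 5 of the 6 (the exception S26), Gzma without 5 (the exception S25), H2-Oa (S23, S24, S25, S27) and Zfp36 (S22, S24, S25, S27) without 4, Dusp1 (S24, S25, S27) and Prf1 (S22, S23, S27) without 3, and Ctsd and Ier3 (S24, S25) and H2-Ab1 and Nkg7 (S22, S23) without 2. The count of 615 became 3666 without S26, 297 without S25, 306 without S27, 307 without S22, 318 without S23 and 337 without S24. It was 230 without S25 and S27, 167 with the closest libraries averaged, 278 in a model of these groups only, 5856 with array weights, 1001 with DESeq2 and 10 with the neutrophil score as a covariate, which moves with the knockout microglia group.

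In transplanted cells the same question was put to the donor genotype. Lipoprotein lipase (Lpl) had 2396 ± 613 normalized reads with wild-type and 266 ± 121 with knockout donors (n = 4 each), a log2 difference of 3.25. No list kept its camera call here with an estimated correlation, and S30 and S31, with oligodendrocyte scores of 10.13 and 10.16, weighed on several lists. Of 29 DAM stage 2 genes 7 were higher and 0 lower (10 higher adjusted over the list alone; median 0.77, adjusted p = 0.496 with an estimated correlation; median 0.34 without S30 and S31), with Ch25h at 1.76, Capg and Itgax at 1.33. The mean log2 value of this list split the knockout donor libraries, with 9.40 in S32 and 9.58 in S35 but 10.24 in S33 and 10.31 in S34, against 10.37 to 10.95 with wild-type donors. In the stage 1 list 3 of 10 were higher (4 adjusted over the list alone; median 0.35, adjusted p = 0.484 with an estimated correlation), Fth1 (0.84), Lyz2 (0.74) and Ctsz (0.40), with Cstb at 0.60 (adjusted p = 0.067). Lipid handling genes were higher in 4 of 22 cases (7 adjusted over the list alone; median 0.31, adjusted p = 0.484 with an estimated correlation; median 0.14 without S30 and S31), among them the LXR receptor Nr1h3 (1.55) and Pltp (0.56). Homeostatic genes were lower with wild-type donors in 5 of 24 cases and higher in 0 (8 lower adjusted over the list alone; median −0.27, adjusted p = 0.431 with an estimated correlation): P2ry12 had 7634 ± 1905 against 15510 ± 2930 (−1.04), with Golm1 at −0.70, Tgfbr1 at −0.67 and P2ry13 at −0.56.

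The glycolysis and inflammatory lists passed camera only with the preset correlation. Of 21 glycolysis genes 11 were higher (14 higher and 1 lower adjusted over the list alone; median 0.51, adjusted p = 0.484 with an estimated correlation; median 0.27 without S30 and S31), with Slc16a3 at 0.87, Aldoa at 0.81, Gapdh at 0.71 and Pgam1 at 0.56. Of 22 cytokine genes 7 were higher (11 adjusted over the list alone; median 0.38, adjusted p = 0.484 with an estimated correlation), with Ccl4 at 1.94, Il1b at 1.85, Cd14 at 0.86 and Cxcl16 at 0.40. Immediate early genes were higher in 7 of 21 cases (12 adjusted over the list alone; median 0.78, adjusted p = 0.484 with an estimated correlation), with Nr4a1 at 1.43, Zfp36 at 0.98, Junb at 0.96 and Fos at 0.90. Other large differences were Myo1e (2.01) and Wfdc17 (1.70) upward and Btaf1 (−1.06), Nr1d2 (−1.02), Rab39 (−0.97), Nufip2 (−0.95), the insulin-degrading enzyme Ide (−0.89), Map3k2 (−0.87) and Ugcg (−0.86) downward.

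The oligodendrocyte, endothelial, and T and NK cell lists also passed camera with the preset correlation only. Of 11 oligodendrocyte genes 6 were higher with wild-type donors (10 adjusted over the list alone; median 3.37, adjusted p = 0.484 with an estimated correlation), with Mog at 5.08, Mal at 4.40, Mag at 1.39 and Mbp at 1.28. The mean log2 value of this list was 10.13 in S30 and 10.16 in S31, against 5.10 and 5.72 in the other wild-type donor libraries and 4.52 to 4.91 with knockout donors. Ttr and Enpp2, both abundant in choroid plexus, each differed by 4.81. Endothelial genes were higher in 2 of 12 cases (5 adjusted over the list alone; median 1.36, adjusted p = 0.496 with an estimated correlation), Vwf (1.55) and Flt1 (1.49), with Esam at 1.94 (adjusted p = 0.0779) and Ly6c1 at 1.45 (adjusted p = 0.0926). T and NK cell genes were lower in 1 of 16 cases (1 adjusted over the list alone; median −1.27, adjusted p = 0.496 with an estimated correlation), Il7r (−1.01), with Gzma (−1.60, adjusted p = 0.115), Klrb1c (−1.54, adjusted p = 0.0993) and Klrd1 (−1.31, adjusted p = 0.125).

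In all, 453 genes were higher with wild-type donors and 361 lower, 213 and 56 of them at least 2-fold, and the groups did not overlap in 13.7% of genes (2.86% from chance alone). The majority turned with edgeR (430 higher and 597 lower), with quantile normalization (287 and 323) and without S32 (335 and 424). Among called named genes Fos, Nr4a1, Lyz2, Pltp, Tgfbr1, Mog and Vwf overlapped between the groups. The DAM stage 2 median was 0.47 without S32, the homeostatic median −0.16 without S32 and −0.42 without S28, and the T and NK cell median −0.61 without S28. The endothelial call ended without S30 or S31, with adjusted p up to 0.0691. The count of 814 rested on a few libraries: it was 113 without S30, 113 without S31, 175 without S34, 396 without S33, 469 without S35 and 1881 without S28. Without both S30 and S31 it was 20, of which 14 were among the 814. Without both, the medians were 0.23 for DAM stage 1, −0.18 for homeostatic, 0.98 for oligodendrocyte, −2.59 for T and NK cell and 0.45 for endothelial genes, the last no longer called (adjusted p = 0.833). It was 67 in a model of these groups only, 30 with the closest libraries averaged, 3447 with array weights, 1695 with DESeq2 and 430 with the neutrophil score as a covariate. Of 44 called named genes 23 kept their call without any 1 library. The other 21, all of which lost it without S30 and also without S31, were Nr1d2, Nufip2, Ugcg, Golm1, Tgfbr1, Fth1, Lyz2, Ctsz, Nr1h3, Pltp, Cxcl16, Nr4a1, Junb, Fos, Il7r, Mbp, Mal, Mog, Mag, Flt1 and Vwf. Leaving out S34 ended 16 of these calls, S35 13, S33 8, S32 7 and S29 4, and Pltp was 0.37 without S34. Without both S30 and S31 only 4 of the 44 kept their call: Trem2, Lpl, Myo1e and Ide. Among the 40 others Mog was then 1.36, Mal 1.57, Mag 0.32, Flt1 0.82, Wfdc17 1.05, Nr4a1 0.81, Fth1 0.53, Aldoa 0.51, Gapdh 0.45, Ctsz 0.24, Golm1 −0.34, Nr1d2 −0.61 and Ugcg −0.54. Other folds stayed about as large though the call was lost: Ttr was 4.46, Enpp2 4.42, Btaf1 −1.08 and Map3k2 −0.86.

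**Figure D2:**
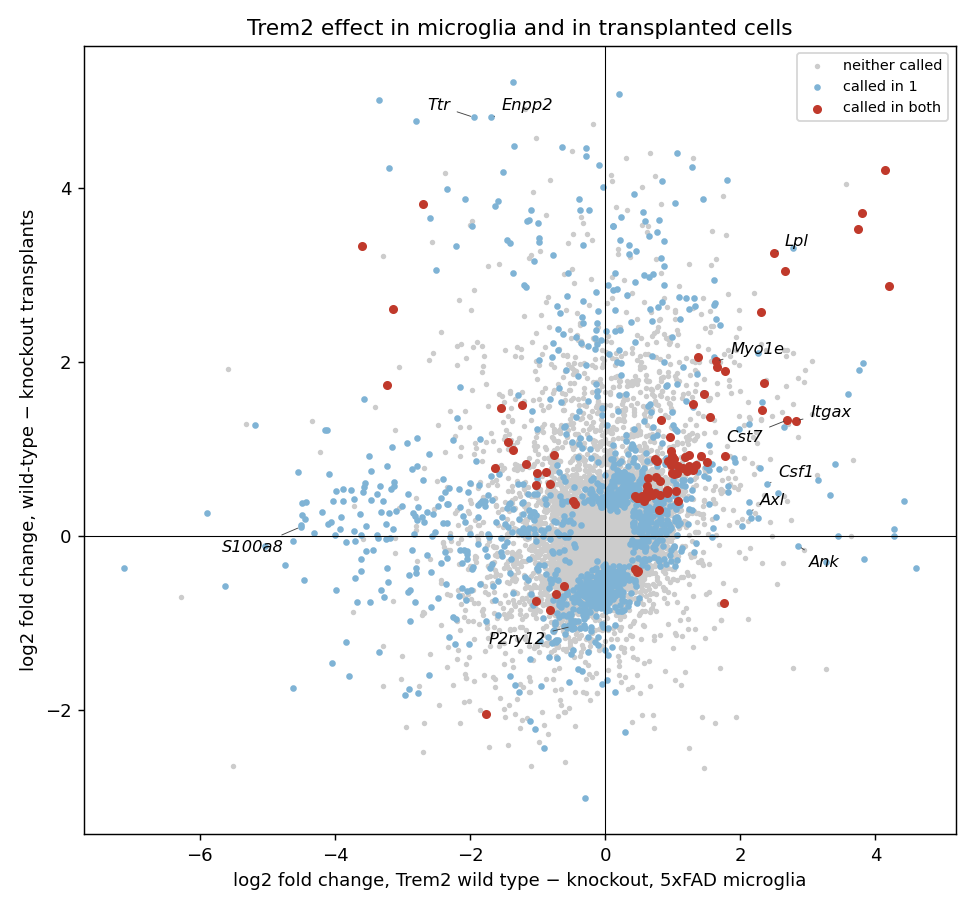
Log2 fold change of Trem2 wild type minus knockout per gene, in 5xFAD microglia (x axis) and in transplanted cells (y axis), without Trem2 itself. Red points were called in both comparisons, blue in 1 and grey in neither, and labels name a selection of genes. Lpl and Itgax lie upper right, while Ank differed by 2.86 in microglia and lay near 0 in transplanted cells.

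Wild-type transplanted cells were then set against wild-type microglia, to show how far cells of circulating origin differ from the resident cells they stand in for. They carried the profile of brain macrophages of hematopoietic origin: 13 of 14 such genes rose and 0 fell (13 adjusted over the list alone), with a median of 2.85. Ms4a7 had 22560 ± 5178 normalized reads (n = 4) against 381 ± 50.8 in microglia (n = 3), and Klra2 rose by 5.76, Clec12a by 4.95 and Cybb, the NADPH oxidase subunit, by 3.61. Of 24 homeostatic microglia genes 21 fell and 0 rose (21 adjusted over the list alone; median −1.07), with Sparc at −4.32, Slc2a5 at −4.16, Ecscr at −4.10 and Siglech at −1.85. Sall1, the transcription factor that marks resident microglia, fell from 6061 ± 278 to 146 ± 70.3 (−5.47).

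MHC class II genes rose in 8 of 9 cases and fell in 1 (8 and 1 adjusted over the list alone; median 1.99, adjusted p = 0.336 with an estimated correlation), with H2-Aa at 2.97, H2-Eb1 at 2.92, H2-Ab1 at 2.90 and Cd74 at 2.76. DAM stage 2 genes split, with 7 higher and 12 lower of 29 (7 and 13 adjusted over the list alone; median −0.30, adjusted p = 0.676 with an estimated correlation): Ccl6 (−2.95), Ank (−2.32) and the protease Ctsl (−2.25) were lower, and Axl was higher (1.99). Monocyte genes rose in 9 of 17 cases (11 adjusted over the list alone; median 0.94, adjusted p = 0.336 with an estimated correlation), with Itga4 at 4.11, Emilin2 at 2.39, S100a6 at 1.91 and Ly6c2 at 1.74. T and NK cell genes rose in 11 of 16 cases (12 adjusted over the list alone; median 2.96, adjusted p = 0.442 with an estimated correlation), with Cd8b1 at 4.63, Prf1 at 3.53, Nkg7 at 3.52 and Lck at 3.46. Of 12 astrocyte genes 4 fell (5 adjusted over the list alone; median −1.26, adjusted p = 0.467 with an estimated correlation), with Slc1a3 at −4.32, Gja1 at −3.33, Cpe at −1.83 and Aldoc at −1.25. The largest other rises were Gdf3 (8.0), Cyp4f18 (4.66), Emilin1 (4.51), Aoah (4.44), Itgal (4.33) and Slamf7 (4.19), and the largest other falls Jam2 (−5.09), Sgce (−4.82), St3gal5 (−4.47), Atp8a2 (−4.43) and Adgrg1 (−4.33).

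In this contrast 1641 genes were higher and 1758 lower, 856 and 952 of them at least 2-fold. The groups did not overlap in 41.1% of genes (5.71% from chance alone). Nor did the called named genes overlap, though those with the largest changes were chosen for this. The estimated correlation kept the calls of homeostatic (adjusted p = 0.00213) and hematopoietic-origin genes (0.000522). The preset call of DAM stage 2 genes ended without S24, S28 or S29 (adjusted p up to 0.138) and with a filter at 50, a pseudocount of 0.5, upper-quartile rescaling or a model of these groups only. Its median was −0.52 without S30 or S31 and −0.74 without both, when the T and NK cell median was 1.59. Aldoc lost its call without S22 (adjusted p = 0.0532). The count of 3399 was 6274 with array weights, 2044 with the closest libraries averaged and 1848 with the neutrophil score as a covariate.

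Knockout transplanted cells against knockout microglia gave the same 2 leading groups. All 14 hematopoietic-origin genes rose (14 adjusted over the list alone; median 2.51), with Ms4a7 at 4.08, Cybb at 3.10, Tmem176a at 2.76 and Tmem176b at 2.23. Of 24 homeostatic genes 16 fell and 1 rose (18 and 1 adjusted over the list alone; median −0.90), with Ecscr at −4.29, Sparc at −3.99, Crybb1 at −3.94 and Slc2a5 at −3.82. Apoe, the lipid carrier, had 2705000 ± 226900 normalized reads (n = 4) against 178100 ± 51140 (n = 3), a rise of 3.97, and took 12.32% of reads in S34, the lowest of the transplanted libraries. Axl rose by 3.84. MHC class II genes rose in 7 of 9 cases and fell in 1 (8 and 1 adjusted over the list alone; median 1.58, adjusted p = 0.386 with an estimated correlation), with H2-Aa at 1.71, H2-Eb1 at 1.60 and H2-DMa at 1.59 but H2-Oa at −1.34.

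The lists that follow passed camera only with the preset correlation. Proliferation genes fell in 15 of 24 cases (18 adjusted over the list alone; median −1.39, adjusted p = 0.456 with an estimated correlation; median −0.33 and no longer called without S25 and S27), with Ccnb2 at −2.16, Ccna2 at −1.36, Tyms at −1.23 and Mcm5 at −0.85. Neutrophil genes fell in 11 of 14 cases (11 adjusted over the list alone; median −2.59, adjusted p = 0.386 with an estimated correlation), with S100a9 at −2.69, Lcn2 at −2.66, Camp at −2.64 and Ngp at −2.60. Monocyte genes fell in 12 of 17 cases and rose in 1 (12 and 2 adjusted over the list alone; median −1.52, adjusted p = 0.386 with an estimated correlation), with Hp at −2.42 and Plac8 at −2.38 but Itga4 at 3.43. T and NK cell genes rose in 11 of 16 cases (13 adjusted over the list alone; median 2.28, adjusted p = 0.414 with an estimated correlation), with Cd3e at 4.40, Cd3g at 4.10, Lck at 3.12 and Il7r at 1.14. All 12 astrocyte genes fell (12 adjusted over the list alone; median −2.23, adjusted p = 0.214 with an estimated correlation), with Slc1a3 at −4.41, Gja1 at −3.09, Clu at −2.19 and Aldoc at −1.71. The largest other rises were Gdf3 (5.62), Emilin1 (4.12), Sorbs3 (3.62), Tmem221 (3.59) and Cp (3.58), and the largest other falls Jam2 (−4.97), Sall1 (−4.88), Sgce (−4.86), Apod (−4.59), Fscn1 (−4.21) and Atp8a2 (−4.21).

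Here 1408 genes were higher and 1654 lower, 638 and 1214 of them at least 2-fold. The groups did not overlap in 27.8% of genes (5.71% from chance alone). Nor did the called named genes overlap, though those with the largest changes were chosen for this. The estimated correlation kept the calls of homeostatic (adjusted p = 0.00899) and hematopoietic-origin genes (0.000654). Without S25 and S27 the proliferation call ended (median −0.33, adjusted p = 0.724) and so did calls of genes such as Ccnb2 (−0.76), Ccna2 (−0.47), Tyms (−0.73), Mcm5 (−0.36), Cd3e (2.85), Cd3g (3.49), Lck (2.44), Aldoc (−1.06) and Apod (−3.22). Plac8 was −1.51, S100a9 −1.67, Camp −1.65, Ngp −1.67 and Gja1 −1.82, all still called. The medians were then −1.67 for neutrophil, −0.88 for monocyte, 1.42 for T and NK cell and −1.29 for astrocyte genes. With the neutrophil score as a covariate the monocyte call ended and the count of 3062 became 912. It was 6477 with array weights.

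Wild-type transplanted cells against knockout microglia is the contrast between the replaced and the resident cells of a knockout brain. Trem2, cell origin and treatment changed together in it. DAM stage 1 genes rose in 7 of 10 cases (8 adjusted over the list alone; median 0.73, adjusted p = 0.286 with an estimated correlation), with Apoe at 4.32, Lyz2 at 3.10, Fth1 at 1.74 and Timp2 at 0.86. Lipid handling genes rose in 13 of 22 cases and fell in 3 (13 and 3 adjusted over the list alone; median 0.94, adjusted p = 0.178 with an estimated correlation), with Cd36, a fatty acid and lipoprotein receptor, at 2.91, Plin2 at 1.27 and Soat1 at 1.12. Lysosome genes rose in 16 of 27 cases and fell in 2 (18 and 2 adjusted over the list alone; median 0.43, adjusted p = 0.286 with an estimated correlation), with Lipa at 1.14 and Gusb at 0.74 but Ctsl at −1.98. DAM stage 2 genes rose in 16 of 29 cases and fell in 8 (16 and 10 adjusted over the list alone; median 0.99, adjusted p = 0.852 with an estimated correlation), with Axl at 4.12 but Ccl6 at −2.18. Trem2 was higher by 3.10 (adjusted p = 4.86e-11). The other genes named in this paragraph moved the same way by mean level in knockout transplants against knockout microglia. Apoe rose there by 3.97 and Axl by 3.84, while mean Ctsl was 8602 against 35060. This contrast alone therefore does not show what Trem2 adds.

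The origin groups were as above: 14 of 14 hematopoietic-origin genes rose (14 adjusted over the list alone; median 2.62), with Ms4a7 at 4.40, Cybb at 2.92, Tmem176a at 2.89 and Tmem176b at 2.35. Of 24 homeostatic genes 20 fell (21 adjusted over the list alone; median −1.20), with Ecscr at −4.80, Crybb1 at −4.42, Sparc at −4.27 and Siglech at −1.95. MHC class II genes rose in 8 of 9 cases and fell in 1 (8 and 1 adjusted over the list alone; median 1.61, adjusted p = 0.286 with an estimated correlation), with Cd74 at 2.09, H2-Aa at 1.73, H2-Eb1 at 1.65 and H2-DMa at 1.61. Neutrophil genes fell in 10 of 14 cases (11 adjusted over the list alone; median −2.44, adjusted p = 0.286 with an estimated correlation), with S100a9 at −2.56, Mmp8 at −2.54, S100a8 at −2.44 and Camp at −2.44. The largest other rises were Gdf3 (6.32), Emilin1 (4.29), Sorbs3 (4.07), Gpnmb (3.93) and Tmem221 (3.65), and the largest other falls Sall1 (−5.16), Jam2 (−5.07), Sgce (−4.98), St3gal5 (−4.54), Slc1a3 (−4.46) and Atp8a2 (−4.45).

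In this contrast 2085 genes were higher and 2153 lower, 809 and 1157 of them at least 2-fold. The groups did not overlap in 31.2% of genes (5.71% from chance alone). Nor did the called named genes overlap, though those with the largest changes were chosen for this. The estimated correlation kept the calls of homeostatic (adjusted p = 0.00376) and hematopoietic-origin genes (0.00195). The preset call of DAM stage 2 genes ended without S26 (median 0.45, adjusted p = 0.708), S30 or S31, without S30 and S31 together (median 0.57), with a pseudocount of 5, a filter at 50 or quantile normalization. Quantile normalization also ended the lysosome call, and the lipid median was 0.58 without S30 and S31. Without S25 and S27 the neutrophil median was −1.39, Mmp8 (−1.40) and S100a8 (−1.32) lost their calls, S100a9 was −1.54 and Camp −1.46, and Gpnmb was 6.60, against 2.60 without S26. The count of 4238 was 2743 without S25, 2644 in a model of these groups only, 6996 with array weights, 2118 with the closest libraries averaged, 2188 without S25 and S27, 2726 without S30 and S31, and 1789 with the neutrophil score as a covariate. With quantile normalization more genes were higher than lower here (2146 and 2129), for knockout transplants against knockout microglia (1593 and 1410) and for wild-type transplants against wild-type microglia (1741 and 1709).

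**Figure D3:**
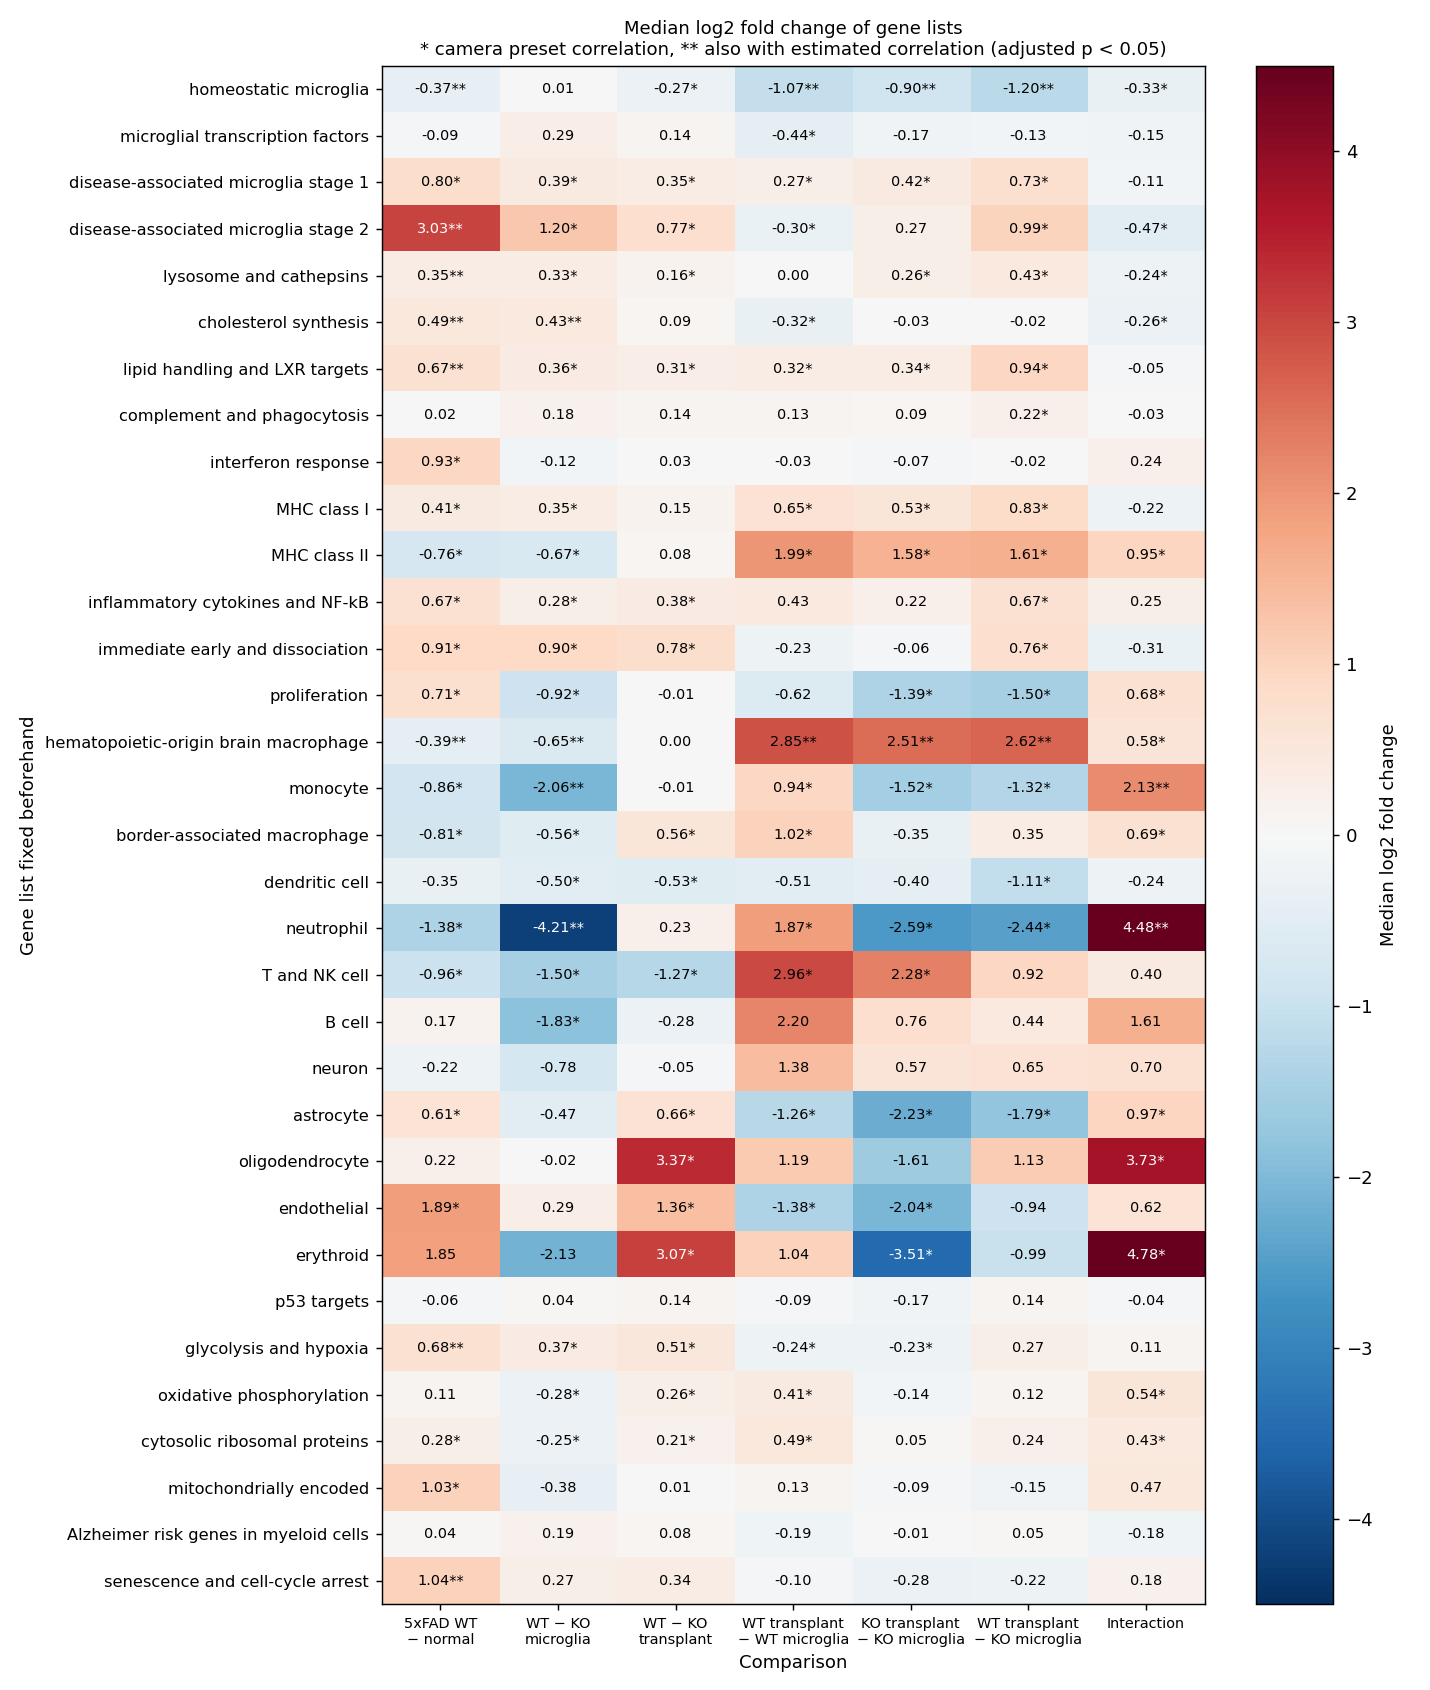
Median log2 fold change of 33 gene lists fixed beforehand (vertical axis) in the 7 comparisons (horizontal axis), with red for higher and blue for lower. A single asterisk marks adjusted p under 0.05 by camera with the preset correlation and a double asterisk also with an estimated correlation. Hematopoietic-origin genes were higher and homeostatic genes lower in each contrast of transplanted cells with microglia.

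The difference between wild-type and knockout cells was then compared between the origins. In transplants only the donor cells differed in Trem2, in knockout hosts, while in microglia the whole mouse differed, so the interaction covers origin, treatment and host genotype. Several DAM genes differed by genotype in microglia and less in transplanted cells: Ank was 1982 ± 20.9 with wild-type and 2154 ± 288 with knockout donors (n = 4 each), and its genotype effect was lower there by 2.97 (value −2.97, adjusted p = 9.3e-09). Axl (−1.85), Csf1 (−1.80), Sulf2 (−1.73), Itgax (−1.49), Dhx33 (−1.33), Il4i1 (−1.31) and Cd34 (−1.29) went the same way. Neutrophil genes also differed in microglia (list median −4.21) and hardly in transplanted cells (0.23). As they were lower in wild-type microglia, their interaction was positive, in 10 of 14 cases (11 adjusted over the list alone; median 4.48), with Camp at 4.63, S100a9 at 4.62, S100a8 at 4.61, Lcn2 at 4.5, Ngp at 4.47 and Mmp8 at 4.34. Monocyte genes had the same pattern, with a median of −2.06 in microglia, −0.01 in transplanted cells and a positive interaction in 10 of 17 cases (14 adjusted over the list alone; median 2.13). Ttr (6.75) and Enpp2 (6.5) were higher with wild-type donors and not called in microglia (−1.94, adjusted p = 0.279, and −1.69, adjusted p = 0.325). Other choroid plexus markers had a median of 4.78, and their mean log2 value was as high in knockout microglia S25 (5.46) and S27 (5.65) as with wild-type donors (4.27 to 5.77). DAM stage 2 genes were lower in 4 of 29 cases (6 adjusted over the list alone; median −0.47, adjusted p = 0.713 with an estimated correlation).

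The interaction called 236 genes higher and 105 lower. With an estimated correlation the neutrophil (adjusted p = 0.0495) and monocyte calls (adjusted p = 0.0236) held. The DAM stage 2 list lost its preset call without S26 (median 0.00, adjusted p = 0.694), and its median was −0.75 without S25 or S27, −0.26 without S28 or S34 and −1.57 without S25 and S27. Csf1 lost its call without S22, S23, S24 or S33, and Dhx33 without 8 of the 14 libraries (S22, S23, S24, S25, S27, S30, S31 and S33). Ttr and Enpp2 lost their calls without S30 and S31 together, with folds of 6.40 and 6.12. They also lost them without S25 and S27 together, with folds of 5.91 and 4.88, when Dhx33 was −0.53. The count of 341 was 1665 without S26, 624 without S28, 219 without S30, 217 without S31, 212 without S25, 200 without S23, 193 without S27 and 185 without S22. It was 4538 with array weights, 875 with DESeq2, 70 with the closest libraries averaged, 163 without S25 and S27, 149 without S30 and S31, and 2 with the neutrophil score as a covariate.

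The genes called between wild-type and knockout 5xFAD microglia were then followed into the transplanted cells, leaving Trem2 out. Of the 614 called in microglia 367 (59.8%, Wilson 95% interval 55.8 to 63.6) had the same sign in transplanted cells, against 59.1% of all tested genes. The interval treats genes as independent, which they are not, so it is too narrow. The 312 genes higher in wild-type microglia had a median of 0.26 in transplanted cells (camera adjusted p = 3.63e-12), a call lost with an estimated correlation (adjusted p = 0.0813, or 0.0471 before adjustment), and 65 were called higher in both, where 11.7 would follow from independence. The 302 lower genes had a median of 0.10 (adjusted p = 0.428), and 5 were called lower in both (9 from independence). These 302 include neutrophil and monocyte marker genes, which other sorted cells could supply. With the neutrophil score as a covariate, which moves with the knockout microglia group, 10 genes were called in microglia, all higher. The same-sign share therefore does not measure a Trem2 effect within microglia alone. Of the genes called in both, 21 went opposite ways. Across 12073 genes, which are not independent replicates, the Pearson correlation of the effects was 0.165 and the Spearman correlation 0.254. The share was 67.4% without S26 and 55.4% without S24.

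Of 456 genes that changed with 5xFAD in wild-type microglia, 325 (71.3%, interval 67 to 75.2) had the same sign for wild-type against knockout donor cells, against 49% of all tested genes. This interval also treats genes as independent, though their estimated correlation was 0.172 in the set that rose and 0.055 in the set that fell. The 341 that rose had a median of 0.38 (camera adjusted p = 1.15e-14), a call lost with an estimated correlation (adjusted p = 0.0813), and 88 were called higher in both (12.8 from independence). The 115 that fell had a median of −0.02 (adjusted p = 0.326). The contrasts set side by side here share no library, but they share the residual variance of each gene, from the limma model of all libraries. A gene with a small variance is more easily called in both. The counts from independence, here and in the adjoining paragraphs, leave this out and may be too low.

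The origin effect was largely shared by the genotypes. Of 3399 genes called in wild-type cells 2935 (86.3%) had the same sign in knockout cells, against 68.2% of all tested genes. Called in both were 797 higher genes (191.4 from independence) and 971 lower genes (240.8), and 71 went opposite ways. The Pearson correlation across genes was 0.691 and the Spearman correlation 0.561. The shared count of 1768 was 2933 with array weights and 720 with the neutrophil score as a covariate.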

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

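The splits and the interaction were set before their results were seen, while the outlier test was widened from fewer lists to all of them after a first run. Within groups of 4, a value was marked when it lay apart from the others by Dixon's ratio, and chance alone marks about 1 in 20. Of 318 such tests 23 were marked. With wild-type donors S28 stood apart for Enpp2 (0.875), Junb (0.845), Myo1e (0.961), P2ry12 (0.897), Plac8 (0.898), S100a9 (0.921), the homeostatic list (0.929) and the immediate early list (0.838). S29 stood apart for H2-Oa (0.866), Sgce (0.93), Slc1a3 (0.871) and the proliferation (0.925), neutrophil (0.935) and B cell lists (0.847). With knockout donors S34 stood apart for Aldoa (0.874), Axl (0.832), Cp (0.943), Emilin1 (0.936) and Sgce (0.835), S33 for Apod (0.907), and S32 for Fth1 (0.921), Hp (0.879) and Mmp8 (0.868).

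The interaction called 341 genes, of which the 16 named under the rule are given here. It called 15 lists with the preset correlation, of which the 2 that also held with an estimated correlation are given. The effect in transplanted cells minus that in microglia was positive for Ttr (6.75), Enpp2 (6.5), Camp (4.63), S100a9 (4.62), S100a8 (4.61), Lcn2 (4.5), Ngp (4.47) and Mmp8 (4.34), and for the monocyte (2.13) and neutrophil lists (4.48). For the neutrophil list this came from microglia (median −4.21), with little difference in transplanted cells (0.23), and for the monocyte list likewise (−2.06 and −0.01). The difference was negative for Ank (−2.97), Axl (−1.85), Csf1 (−1.8), Sulf2 (−1.73), Itgax (−1.49), Dhx33 (−1.33), Il4i1 (−1.31) and Cd34 (−1.29).

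Other splits of the same libraries were counted for each comparison. For 5xFAD against normal microglia (457 genes, highest other split 0) and for Trem2 in microglia (615, highest other 5) the 10 splits are too few for a share under 0.05 (1 of 10 in each). If all libraries are separate samples, the share was under 0.05 for Trem2 in transplanted cells (814 genes, highest other 268, 1 of 35 splits). The same held for wild-type transplant against wild-type microglia (3399, highest other 2633, 1 of 35) and against knockout microglia (4238, highest other 2944, 1 of 35). It also held for the interaction (341, highest other 575, 3 of 100), though there another split called more genes than the real groups. A share of 1 of 35 is the smallest those splits can give, and the shares were not adjusted over the comparisons. Chance is therefore not excluded. For Trem2 in transplanted cells S30 and S31 were close (chi-square per degree of freedom 5.01, against 37.69 to 60.19 for the other pairs of that group) and count as separate in the splits, while 30 genes were called with the closest libraries averaged and 20 without both. By the count of genes alone the share was not under 0.05 for knockout transplant against knockout microglia (3062 genes, 2 of 35 splits). There, setting S26 with S32, S33 and S35 against the rest called 3679. The real groups did not overlap in 27.8% of genes against 5.71% from chance alone. That percentage was not counted for the other splits, and 5.71% takes the close libraries S25 and S27 as separate. It therefore does not decide between the real groups and that split.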

How the results depend on the processing

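Averaging the closest libraries, leaving out S25 and S27 or S30 and S31, and the neutrophil covariate were chosen after seeing the data, and the other alternatives were planned. No paired analysis was possible because the columns map only to groups. The covariate moves with the knockout microglia group, and the cause of the other shifts was not tested. For 5xFAD against normal microglia (457 genes) a model of the compared groups only called 1757, array weights 2227, DESeq2 769, an added 2-fold threshold 277 and averaged closest libraries 247, with 272 to 325 leaving out 1 library. For Trem2 in microglia (615) these gave 278, 5856, 1001, 362 and 167, with 230 without S25 and S27, 10 with the covariate and 297 to 3666 leaving out 1 library. For Trem2 in transplanted cells (814) they gave 67, 3447, 1695, 269 and 30, with 20 without S30 and S31, 430 with the covariate and 113 to 1881 leaving out 1 library. For wild-type transplant against wild-type microglia (3399) array weights gave 6274, the 2-fold threshold 1808, averaged libraries 2044 and the covariate 1848. For knockout transplant against knockout microglia (3062) array weights gave 6477, the 2-fold threshold 1852 and the covariate 912. For wild-type transplant against knockout microglia (4238) the compared groups only gave 2644, array weights 6996, the 2-fold threshold 1966, averaged libraries 2118, no S25 and S27 2188, no S30 and S31 2726, the covariate 1789, and leaving out 1 library 2743 to 5879. The interaction (341) gave 4538 with array weights, 875 with DESeq2, 70 with averaged libraries, 163 without S25 and S27, 149 without S30 and S31, 2 with the covariate and 185 to 1665 leaving out 1 library. The carry-over of Trem2 genes (59.8%) was 54.8% at 2-fold, 53.6% with averaged libraries, 55.5% without S25 and S27, 88.9% with the covariate and 55.4% to 67.4% leaving out 1 library. The carry-over of the 5xFAD response (71.3%) was 55.5% with the compared groups only, 57.7% with array weights, 65.2% with DESeq2 and 67.4% to 75.8% leaving out 1 library. The shared origin effect (1768) was 2933 with array weights, 1122 at 2-fold and 720 with the covariate. Lists were marked as reversed, by camera direction alone, only when libraries were left out or the covariate was used. The values that follow are list medians in those runs, which did not decide the mark. Without S25 and S27, Trem2 in microglia gave interferon 0.89, proliferation 0.41, oxidative phosphorylation 0.15, ribosomal 0.26 and mitochondrial genes 0.93, and the covariate gave interferon 0.60, proliferation 0.73, dendritic 0.14, B cell 2.12 and astrocyte genes 0.90. In transplanted cells without S30 and S31, MHC class II genes were −0.24 and ribosomal genes −0.11. For knockout transplant against knockout microglia, leaving out S25 and S27 gave DAM stage 2 0.83 (0.27 with all libraries, where only the camera direction was down), immediate early −0.31, oxidative phosphorylation 0.29 and mitochondrial genes 1.11, the covariate immediate early −0.26 and glycolysis genes 0.08, and leaving out 1 library interferon −0.67 to 0.13. For wild-type transplant against knockout microglia, mitochondrial genes were 1.06 without S25 and S27 and interferon genes −0.49 to 0.29 leaving out 1 library. In the interaction, leaving out S25 and S27 gave interferon −0.88, proliferation −0.26, ribosomal −0.039 and mitochondrial genes −0.90, and leaving out S30 and S31 gave T and NK cell genes −0.70. There the covariate gave lipid −0.47, interferon −0.57, immediate early 0.63, proliferation −1.04, dendritic −0.43, B cell −2.76, astrocyte −0.37 and glycolysis genes −0.30. No gene named under the rule turned direction in an alternative run when it was called in that run or in the main one. Sign changes of genes called in neither were not counted. The lists that the named genes represent were chosen after results were seen. At 16044078 to 30606394 reads and 3 or 4 libraries per group, the self-test recovered 4% (interaction) to 34% (Trem2 in transplanted cells) of 1.5-fold changes, so smaller changes may be missed.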

Other observations

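The tests of the neutrophil effect by origin, of the range over 4 libraries and of the DAM stage 2 list were chosen only after the result was seen, as were the neutrophil covariate and the libraries left out. Some further lists follow. In 5xFAD microglia against normal microglia the hematopoietic-origin list fell in 4 of 14 genes (median −0.39) and the senescence list rose in 4 of 10 (median 1.04), both also with an estimated correlation (adjusted p = 0.0279 and 0.0247). Border-associated macrophage genes fell in 3 of 14 cases (median −0.81; adjusted p = 0.0759 with an estimated correlation). In wild-type against knockout microglia 5 glycolysis genes were higher and 1 lower of 21 (median 0.37; adjusted p = 0.266 with an estimated correlation). There 3 of 10 DAM stage 1 genes were higher (0.39; adjusted p = 0.41 with an estimated correlation), and 4 lipid handling genes were higher and 1 lower of 22 (0.36; adjusted p = 0.302 with an estimated correlation), both preset calls lost without S26 (adjusted p = 0.318 and 0.121). In wild-type transplants against wild-type microglia 8 of 13 MHC class I genes rose (median 0.65; adjusted p = 0.442 with an estimated correlation), 8 of 30 ribosomal protein genes rose (0.49; adjusted p = 0.64) and 7 of 28 oxidative phosphorylation genes rose (0.41; adjusted p = 0.64). Complement and phagocytosis genes rose in 7 and fell in 6 of 22 cases there (0.13), microglial transcription factors fell in 6 of 14 (−0.44; adjusted p = 0.442), and Alzheimer risk genes rose in 5 and fell in 9 of 27 (median −0.19, mean 0.01). Dendritic cell genes fell in 2 of 11 cases (−0.51), B cell genes rose in 3 and fell in 1 of 6 (2.20), and 1 of 8 neuron genes rose (1.38). The dendritic list shares Siglech with the homeostatic list and holds Fscn1, also abundant in the microglia libraries. Mean Siglech went from 28670 to 7971 and Fscn1 from 9582 to 617.6, so the fall need not be of dendritic cell RNA. Neither the 12 mitochondrially encoded genes (0.13) nor the 5 erythroid genes (1.04) held a called gene by limma in that contrast, and p53 targets rose in 1 and fell in 3 of 15 cases (−0.09). Erythroid genes had a median of 3.07 for wild-type against knockout donors, with 0 of 5 called over all genes by limma and 5 adjusted over the list alone (adjusted p = 0.496 with an estimated correlation; preset call lost without S35, adjusted p = 0.109).

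Neutrophil RNA was higher in every knockout microglia library than in wild-type 5xFAD microglia. A candidate source is neutrophils sorted with the microglia, since a CD45+CD11b+ gate does not remove them. A second list of neutrophil genes that shares no gene with the first had a median of −3.72, with 17 of 18 lower in wild-type microglia. A Trem2 effect alike in both origins was tested by the interaction of the list and did not hold (adjusted p = 0.0495, close to the threshold). An effect of Trem2 on neutrophils in the brain, the knockout host of both transplant groups, and differences in blood removal or sorting, stay open.

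Oligodendrocyte genes and Ttr and Enpp2 were higher with wild-type donors. RNA from oligodendrocytes may explain the former, though a CD45+CD11b+ gate should remove such cells: a second oligodendrocyte list had a median of 3.61, positive in 18 of 18 genes with 2 called, and of its abundant genes, looked at after the values were seen, Tubb4a was 2696.9 against 24.6 and Trf 20192.4 against 14459.1. RNA from choroid plexus, which the gate should also remove, may explain the latter, as other choroid plexus markers had a median of 3.21, positive in 15 of 15 genes with 7 called, but their score was also 3.98 in the knockout donor library S35 (1.26 to 1.96 in S32 to S34) and 5.46 and 5.65 in knockout microglia S25 and S27, against 4.27 to 5.77 with wild-type donors. A donor effect alike in all 4 libraries was not seen, since the second oligodendrocyte score ranged by 5.67 over them, against a mean difference of 3.08 and a range of 0.31 with knockout donors. All 4 wild-type donor libraries (3.23, 3.41, 8.9 and 8.75) nevertheless lay above all 4 knockout donor libraries (2.82 to 3.13), so a smaller donor effect stays open, as does how such RNA passed the gate.

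DAM stage 2 genes were higher with wild-type donors (median 0.77). Other-cell RNA in S30 and S31 was tested as a source: without them the median was 0.34, just under the bound of 50% set for this test. These libraries had the highest list scores with wild-type donors (10.91 and 10.95, against 10.37 and 10.65). Leaving them out lowers the median whatever the cause, so the drop cannot tell whether other-cell RNA accounts for part. Whether a difference by donor holds is open. Without S30 and S31 the list passed camera with the preset correlation (adjusted p = 1.69e-05), but with all libraries its call was lost with an estimated correlation (adjusted p = 0.496). Knockout host microglia left in the knockout donor libraries could lower the list there, but the median against knockout microglia (0.27) does not settle it. Mean levels of Sall1, Jam2 and Sparc there were 187.1, 80.85 and 4815, against 5451, 2433 and 73630 in knockout microglia and 145.9, 80.14 and 3884 with wild-type donors. For these genes the values argue against a large share of host microglia. P2ry12 was higher with knockout than wild-type donors (15510 against 7634), though Jam2 was almost equal (80.85 against 80.14), so P2ry12 does not decide it. A small share of host microglia stays open. The knockout donor libraries were also uneven: the list score was 9.40 in S32 and 9.58 in S35, but 10.24 in S33 and 10.31 in S34, near S28 (10.37), and Gpnmb was 4888 and 4105 in S33 and S34 against 703.6 and 1317, while Spp1, looked at after the values were seen, was 18260 and 26710 against 1103 and 701.8.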
